A study of Mus musculus with 12 samples.

How the data were processed

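Pancreas tissue was digested with collagenase, red blood cells were lysed and dead cells removed, and libraries were made with the 10x Chromium 3-prime kit (version 3 chemistry), per the labels' protocols. This droplet method tags each captured transcript with a cell barcode and a unique molecular identifier (UMI), so that counts are of molecules and not of amplified copies. Reads were handled with fastp and Cell Ranger 3.0.0 against genome build mm10, per the submitters' processing notes. How cells and genes were chosen before deposit is not given in the sources used here.

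The deposited table held 19919 genes and 1246 cells, of which 18251 genes had a value above 0. Its values are natural log values that the authors made as the logarithm of 1 plus the UMI count divided by a factor of the cell, as read from the values themselves. After the logarithm was undone, all 5171315 values above 0 were whole multiples of the smallest value in their cell within a tolerance of 0.01 (100%), so the UMI counts could be recovered. The factor was not the cell's total, since the scaled values of a cell summed to between 8221 and 66011, with a median of 12162 in the G12D and 18774 in the wild-type cells, and how the authors computed it is not stated. Scaled levels are therefore not UMIs per 10000 UMIs, and over all cells they run higher in the wild-type library, so the choice of scale shifts folds between the libraries. A single UMI was worth a median of 0.614 in the G12D and 1.17 in the wild-type cells. The table had 0 rows for mitochondrially encoded genes, so their share could not be used as a sign of cell quality.

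Cells were tied to groups by the start of their names, which matches the sample titles of the Kras G12D group and of the second wild-type set. All 1246 cells matched. The 4 samples of the first wild-type set had no matching cell names and were not analysed here. The names did not separate the 4 numbered samples of a group, and nothing in the labels said whether these were separate animals or parts of 1 library, so each group counted as 1 library. The G12D group was to be compared with both wild-type sets, with no test where each group was 1 library, and this left 1 comparator. The planned levels per 10000 were replaced by the scaled levels that the deposited unit gives, with UMIs per 10000 UMIs as an alternative.

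Computation used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5 and igraph 0.11.9. Figures were drawn with matplotlib 3.10.9. Each library was clustered on its own from the deposited log values with 2000 variable genes, values scaled and limited to 10, 20 principal components, 15 neighbours and resolution 1 (alternatives 0.5 and 2). Clusters were named from 21 marker lists fixed before the data were examined. A name needed at least 3 detected markers, each in at least 25% of the cells. A cluster of low depth for its library also needed a marker of its class among its 10 leading genes. A marker of another class among the leading genes did not by itself remove a name, so W0, G12 and G14 kept theirs with 0 markers of their own class and 1 of another there, and an alternative added after the data were seen left them out. Limits set after the data were seen kept some clusters unnamed, namely a mean marker score of 0.9 for intestinal or non-epithelial genes, or 2 lymphocyte genes among the 10 leading genes. The intestinal limit was at first 1 and was lowered so that a cluster of 12 cells with the same genes was included. No doublets were removed, and an alternative left out cells that carried markers of 2 classes, by a rule set after the data were seen.

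Groups were compared by the mean scaled level per gene over cells. Folds in the text are ratios of mean levels, and log2 folds were taken after adding a pseudocount of 0.1, which understates the difference of low genes. Genes with a level of at least 0.5 in the higher group and at least 2-fold apart were ranked by log2 fold, and the first 12 in each direction were named, with Ly6d and Kras always. The rule asked for the same direction against both wild-type sets and was applied with 1. For gene lists, up to 4 members with a level of at least 0.1 served as examples. Ductal-like clusters were compared by number, because some had a marker of another class among their leading genes. Acinar-like cells were not compared between libraries, because the G12D library held 14 and the minimum was 50.

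No p-value was computed between genotypes, because cells are not replicates. Shares above 0 carry exact Clopper-Pearson 95% intervals, a share of 0 the upper limit of 3 cells of the total, and UMI sums and their ratios exact Poisson 95% intervals, all for counting error only. A gene with 0 UMIs in a group was set against a floor of 3 UMIs over that group, and such folds are rounded to the nearest digit. Each of the 27 gene lists fixed in advance was described by its median log2 fold and the percentile of that median among 10000 random lists of the same size drawn from 20 bins of mean expression. Lists in the outer 2.5% at either end are said to stand apart, which describes these libraries and tests no condition. Shares of cells with a UMI were also taken after thinning each cell to 5000 UMIs.

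The steps were tested on simulated cells drawn from the G12D profile for the comparison of ductal-like clusters, with 400 and 92 cells, 3133 genes above the level limit and 200 changed genes. All simulated UMIs were recovered (100%). Genes changed 2.5-fold and 4-fold upward passed 2-fold in 92% and 100% of cases, genes lowered to 0.4 and 0.25 of their level in 82% and 94%, and unchanged genes in 0%. Both simulated groups came from the same profile, so these rates cover counting error in simulated cells only. They give no error rate for the measured comparison, which held 611 and 97 cells in several clusters. There, wild-type clusters W0 and W1 of the same library had 230 of 5197 genes 2-fold apart. A list of 20 raised genes reached percentile 100, and 7 of 100 unchanged lists fell in the outer 2.5% at either end.

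Alternatives covered the pseudocount, the minimum level, the scaling, the weight of cell classes and clusters, single clusters left out, the clustering resolution, cells with markers of 2 classes, the detection threshold and the depth per cell. Coordinates of Ly6d and Kras came from the GENCODE annotation of GRCm38, the assembly also called mm10.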

Results

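Single-cell RNA profiles were examined from the pancreas of mice with chronic pancreatitis provoked by caerulein, a cholecystokinin analog that overstimulates acinar cells. The mice carried either wild-type Kras or the G12D change, an oncogenic mutation of Kras, the gene that is mutated in most pancreatic cancers. The series asks how pancreatic tumors start, and its title names LY6D, a small surface protein of the Ly6 family, as a marker of tumor-initiating cells. The labels list 12 samples, of which 4 are Kras G12D, 4 are Kras wild type and 4 are a second wild-type set. Cell names tied 1013 cells to the G12D group and 233 cells to the second wild-type set, and the first wild-type set was not analysed here. The G12D cells held 25339278 unique molecular identifiers (UMIs), with a median of 18351 per cell (interquartile range 9672 to 30994) and a median of 4279 genes. The wild-type cells held 6515590 UMIs, with a median of 14661 per cell (interquartile range 7624 to 30961) and a median of 2963 genes.

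Cell names did not show which of the 4 numbered samples a cell came from, so each group counted as 1 library with no replicate, and no test between genotypes was possible. Differences below are therefore described as higher or lower in the cells of 1 library. All intervals are 95% intervals for counting error only and do not cover differences between animals. The run codes in the labels also differ between the groups, so genotype and library batch cannot be told apart in any comparison. Levels are means over cells of the deposited scale after the logarithm was undone, called scaled levels here.

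The first question was which kinds of cells each library held. In the G12D library, 611 cells (60.3%, exact binomial interval 57.2 to 63.3%) lay in 8 clusters called ductal-like, in which duct markers scored highest among the epithelial classes. Another 190 cells (18.8%, 16.4 to 21.3%) lay in 3 gastric mucous-like clusters (G1, G3 and G4), which carried stomach-type mucins and trefoil factors. That name was weaker in G3, which had 0 gastric markers among its 10 leading genes, mostly cell cycle genes. G1 (80 cells) had 2 there, but a median of only 4650 UMIs and 1568 genes per cell. Acinar-like cells, the enzyme-secreting cells of the pancreas, made up 14 cells (1.38%, 0.758 to 2.31%). In the wild-type library, 91 cells were acinar-like (39.1%, 32.8 to 45.6%) and 97 cells were ductal-like (41.6%, 35.2 to 48.2%), while no cluster was gastric mucous-like (0 of 233 cells, which allows a share of up to 1.29%, or 3 cells of the total). The ductal-like name was weakest in G12, G14 and W0, which had 0 duct markers and 1 marker of another class among their 10 leading genes. Of the other ductal-like clusters only G5 and G7 had a duct marker among those genes, so elsewhere the name rested on the marker score. With G12, G14 and W0 left unnamed the ductal-like shares were 43.7% in the G12D and 19.7% in the wild-type library.

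The remaining clusters stayed unnamed. In the G12D library they held 198 cells (19.5%, 17.1 to 22.1%). Of these, 128 cells were led by intestinal genes, 43 had lymphocyte genes among their leading genes, 14 carried macrophage markers and 13 carried fibroblast markers. In the wild-type library 45 cells (19.3%, 14.45 to 24.98%) were unnamed, of which 25 carried fibroblast markers (W3) and 20 had leading lymphocyte genes (W5). Both clusters still scored highest on acinar markers, at 5.06 in W3 and 5.44 in W5. The acinar-like W4 and W6 scored 5.28 and 5.41, so the wild-type acinar-like share leaves out cells with an acinar profile. The lymphocyte genes rested on few cells in both libraries, with Gzma in 1 of 43 G12D cells and Cd2 in 4 of 20 wild-type cells. Collagenase digestion, dead-cell removal and the choice of cells before deposit can all set such shares. The genes that define the classes also differed between the libraries, so the shares describe each library and were not ranked between them. A coarser clustering moved the gastric mucous-like share of the G12D library to 29.4%.

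Over all cells, genes of stomach-type mucous epithelium were higher in the G12D library and genes of pancreatic digestive enzymes were higher in the wild-type library. Tff1, a trefoil factor of gastric mucus, had a mean scaled level of 67.4 in G12D cells and 0 UMIs in wild-type cells, so it was at least 2565-fold higher against a floor of 3 UMIs over the group. The gastrokines Gkn1 and Gkn2 were likewise at least 768-fold and at least 299-fold higher. Try4, a trypsinogen, had a level of 0.190 in G12D and 990 in wild-type cells, 5215-fold lower in G12D (Poisson interval 4486 to 6101). The share of acinar-like cells (1.38% against 39.1%) stood beside each of the enzyme differences.

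The other genes picked by the fixed rule included genes of intestinal epithelium. S100a6, a calcium-binding protein, was 185-fold higher in G12D cells, at 133 against 0.720. Lgals4, an intestinal galectin, was 554-fold higher, and Ctla2a, a cysteine protease inhibitor, 364-fold higher. Mcub.1, a second table entry for Mcub, which encodes a mitochondrial protein, was 1222-fold higher. The first Mcub entry was not among the named genes. Mptx1, a mucosal pentraxin, Lypd8, a Ly6-type protein of colonic epithelium, and Mcpt2, a mucosal mast cell protease, had 0 UMIs in wild-type cells and were at least 542-fold, 483-fold and 321-fold higher. Phgr1 and the intestinal mucin Muc2 each had 1 UMI in the wild-type cells, with ratios of 18593 (interval 3337 to 734425) and 10222 (1834 to 403758). Without the 3 intestinal-led clusters (128 cells), 21 of the 24 named genes still passed. Muc2, Mptx1 and Lypd8 did not, with log2 folds that fell from 6.39 to 0.71, from 7.16 to 2.01 and from 6.998 to 2.41 (the last pair then under the minimum level), so their ratios over all cells came mostly from those clusters and not from the library at large.

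Among the genes lower in G12D cells, Pnlip (pancreatic lipase) was 1699-fold lower, Cela2a (an elastase) 969-fold, Ctrl (a chymotrypsin-like protease) 451-fold and Pla2g1b (pancreatic phospholipase) 1148-fold. Rnase1, a secreted ribonuclease, was 325-fold lower, and the carboxypeptidases Cpb1 and Cpa2 were 251-fold and 299-fold lower. Prss1, Gm5771, 1810009J06Rik and 2210010C04Rik were 44913-fold, 9766-fold, 875-fold and 451-fold lower. These 4 genes and Try4 belong to the trypsinogen family, whose near-identical copies can share reads, so the values of single copies are uncertain.

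Of the fixed gene lists, the acinar digestive enzymes had 30 of 31 measured members at least 2-fold lower in G12D cells (median log2 fold -6.21, percentile 0 among 10000 matched random lists). Gastric metaplasia genes had 20 of 23 members higher (median 3.46, percentile 100), and ductal and progenitor genes had 11 of 24 higher and 2 lower (0.80, percentile 99.9), with Krt7 and Krt19, keratins of duct cells, 25.03-fold and 21.95-fold higher. MAPK output genes, which respond to signaling downstream of RAS, had 13 of 22 higher and 1 lower (1.34, percentile 100), and Phlda1 and Emp1 were 21.3-fold and 22.4-fold higher. The unfolded protein response list, which acinar cells use heavily, had 12 of 20 lower (-1.41, percentile 0), with Sel1l, part of the machinery that removes misfolded proteins, 10.3-fold lower. The acinar transcription factors had 4 of 9 lower and 1 higher (-0.93, percentile 0.0250), with Rbpjl and Bhlha15, regulators of the acinar secretory program, 83.3-fold and 82.0-fold lower. The Reg family and acinar injury list went both ways, with 4 members higher and 6 lower (-1.07, percentile 0.0300), but it no longer stood apart with the mean of members (-0.56). Its median became 0.02 with UMIs per 10000 UMIs of each cell, where it still stood apart on the lower side. In all, 21 of 25 lists stood apart over all cells. The others on the higher side were the Ly6 family (1.27), squamous or basal genes (1.99), NF-kB and inflammatory cytokines (0.75), senescence and p53 targets (1.67), glycolysis and hypoxia (1.02) and inflammatory macrophage genes (1.57). Those on the lower side were AP-1 and dissociation response (-0.33), interferon response (-1.20), MHC class II (-0.98), cell cycle (-0.74), extracellular matrix (-0.80), inflammatory fibroblast (-1.06), alternative macrophage (-0.72) and erythroid genes (-1.37). Some of them had members both ways. AP-1 and dissociation response had 5 members higher and only 2 lower, against the side of its median, extracellular matrix 5 and 5, inflammatory fibroblast 2 and 7, alternative macrophage 2 and 3, and NF-kB and inflammatory cytokines 9 and 1. Of these the Ly6, AP-1, extracellular matrix, alternative macrophage and erythroid lists lost their place under at least 1 alternative. AP-1 (0.20) and extracellular matrix (0.0939) changed sign with the mean of members, and extracellular matrix also with UMIs per 10000 UMIs (0.46). The share of cells in clusters with fibroblast markers (1.28% in G12D against 10.7%) stood beside the extracellular matrix and inflammatory fibroblast differences.

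In total 4390 genes were compared over all cells, and 64.2% of those at least 2-fold apart were higher in G12D cells. That split rested on the scaling, since it was 27.8% with the enzymes left out of each cell's total and 81.1% with UMIs per 10000 UMIs.

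The next comparison asked which genes differed between libraries within ductal-like cells. In the 8 G12D clusters (G0, G5, G6, G7, G11, G12, G14 and G15, 611 cells) gastric and senescence-related genes were higher than in the 3 wild-type clusters (W0, W1 and W2, 97 cells). Interferon-response genes were lower. S100a6 was 156-fold higher, at 147 against 0.946, and was 2-fold higher in each of the 8 clusters. Apoe, a lipid carrier also abundant in macrophages, was 45.7-fold lower, at 0.844 against 38.6, and Prox1, a homeobox regulator of pancreas development, was 54.8-fold lower, at 0.161 against 8.80, and each was 2-fold lower in 8 of 8 clusters. Median depth was 18246 UMIs in the G12D and 16732 in the wild-type ductal-like cells.

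Some ductal-like clusters had a marker of another class among their 10 leading genes (Gkn3 in W0, Rgs5 in G12, Mcpt8 in G14, Msln in G7, and Ly6d and Dmbt1 in G5), and in W0, G12 and G14 these outnumbered the duct markers there. Values are therefore pooled over the numbered clusters, with the number of G12D clusters that were 2-fold apart and, for some genes, the range over clusters, and do not describe a ductal cell type. Among genes higher in G12D, Tff2, another trefoil factor, was 75.3-fold higher (55.2 against 0.733, clusters 3.21 to 356) and Tff1 at least 316-fold higher (9.88 against 0 UMIs, clusters 0.528 to 72.4). Ctse, a gastric-type cathepsin, was 98.4-fold higher, Anxa1, an annexin, 61.0-fold higher, and Mcub.1 1046-fold higher. Ctla2a, Prss22 (a tryptase-like protease), Sox11 (a developmental transcription factor) and Mcpt2 had 0 UMIs in the wild-type clusters and were at least 730-fold, 199.7-fold, 195-fold and 101-fold higher, with Ctla2a from 0.354 in G0 to 42.1 in G15. Fn1, which encodes the matrix protein fibronectin, was 60.8-fold higher (30.6 against 0.504) and ranged from 0.605 in G0 to 80.0 in G15. Msln, encoding mesothelin, had 3 wild-type UMIs and a ratio of 111 (interval 38.1 to 540.5). Fn1 and Mcpt2 were 2-fold higher in 7 of the 8 clusters and the other 10 named genes in all 8.

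Genes lower in the G12D clusters included Ces1d, a carboxylesterase, at 398-fold (0.0274 against 10.9), Dcdc2a, a doublecortin-domain gene, at 98.0-fold, and Fgfr3, a fibroblast growth factor receptor, at 96.7-fold. Ttr, which encodes transthyretin, was 42.6-fold lower, at 0.483 against 20.6. The other 6 named genes were acinar enzymes or trypsinogens. Try4, 2210010C04Rik and Cela2a were 726-fold, 492-fold and 198-fold lower, while Gm5771, Pnlip and Prss1 had only 1, 2 and 1 UMIs in G12D and ratios of 9755 (1745 to 385819), 3727 (1027 to 30846) and 3964 (708 to 156893). Beside these stood a measured background, since enzymes in the wild-type ductal-like cells had a median level of 0.691% of that in the acinar-like cells of the same library. All 12 named genes were 2-fold lower in 8 of 8 G12D clusters.

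Example genes of the lists below were at least 2-fold apart in all 8 G12D clusters unless stated. Among the epithelial gene lists, gastric metaplasia genes had 18 of 21 measured members at least 2-fold higher and 1 lower (median log2 fold 2.71, percentile 100). Squamous or basal genes had 5 of 7 higher (2.14, percentile 100), including Sfn, the epithelial protein stratifin, at 17.3-fold, and Ly6d itself (2-fold in 4 of 8 clusters). Of the 16 list genes in the table only those 7 reached the minimum level, Trp63, the regulator of squamous cells, had a level of 0 and the keratins Krt14 and Krt6a were at 0.00463 and 0.00134, so this does not show a squamous program. The Ly6 family had 4 of 7 higher and 1 lower (1.45, percentile 99.99), with Ly6a, a stem-cell antigen in mouse, 18.4-fold higher pooled and at least 2-fold higher in all 8 clusters. By cluster the Ly6 list did not stand apart in G7 (-0.09), G11 (0.03), G14 (0.26) and G15 (-0.13). The Reg family and acinar injury list had 6 of 10 higher (1.71, percentile 99.99), with Reg3b, a secreted antimicrobial lectin, 18.3-fold higher (2-fold in 5 of 8 clusters, 0.0939 to 24.2) and Nupr1, a stress-response gene, 9.27-fold higher. The Reg list did not stand apart in G14 (0.10) and G15 (-0.41). Ductal and progenitor genes went both ways, with 10 of 24 higher and 6 lower (0.53, percentile 99.2). By cluster this list stood apart on the higher side only in G5 (0.77) and G6 (0.86). In G14 and G15 it stood apart on the lower side, with 13 of 24 members lower in each (-1.05, percentiles 0.04 and 0.02). Krt7 was 23.4-fold higher, whereas Onecut1, a duct and progenitor transcription factor, was 66.7-fold lower. Acinar digestive enzymes had 27 of 29 lower and 1 higher (-3.20, percentile 0). The exception was Dmbt1, a mucosal defense protein that is also on the gastric list, at 13.7-fold higher pooled. It was 2-fold higher in 4 clusters and 2-fold lower in 2, from 0.135 in G15 to 142.9 in the 30 cells of G5, so the pooled value leans on G5. Acinar transcription factors had 4 of 6 lower and 1 higher (-1.28, percentile 0.330), with Nr5a2, an acinar and stem-cell regulator, 20.3-fold lower. That list and the ductal and progenitor list no longer stood apart when the mean of members replaced the median, and the acinar transcription factors also not without W0, G12 and G14 (-0.996).

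Among the signaling lists, senescence and p53 targets had 11 of 14 members higher (1.95, percentile 100), and Cdkn2b, an inhibitor of cell-cycle kinases, was 81.1-fold higher pooled, from 0.385 in G5 to 4.69 in G15 against 0.0346, and at least 2-fold higher in all 8 clusters. MAPK output genes had 9 of 23 higher and 3 lower (0.71, percentile 100), but by cluster the list did not stand apart in G0 (0.21), G7 (-0.10) and G14 (-0.04). Emp1 and Phlda1, both induced by growth factor signaling, were 31.4-fold and 14.8-fold higher, while the immediate-early genes Egr1 and Fos were 4.11-fold and 3.14-fold lower (Fos in 7 of 8 clusters). The AP-1 and dissociation response list, which also reacts to tissue digestion, had 11 of 18 lower and 3 higher (-1.47, percentile 0). Socs3, a feedback inhibitor of cytokine signaling, was 5.20-fold lower, and Hspa1a, a heat-shock protein, was 5.29-fold higher. Glycolysis and hypoxia genes had 7 of 19 higher and 1 lower (0.54, percentile 99.8), with hexokinase Hk2 16.98-fold and pyruvate kinase Pkm 7.15-fold higher. NF-kB and inflammatory cytokine genes had 6 of 17 higher and 2 lower (0.25, percentile 98.7), with the neutrophil chemokine Cxcl2 14.6-fold higher and the adhesion molecule Icam1 10.02-fold lower. That list no longer stood apart without cluster G5 (0.19) or without W0, G12 and G14 (-0.00945). The inflammatory macrophage list had 5 of 7 higher (1.37, percentile 99.99), with the cytokine Il1a at least 31.3-fold higher and Ptgs2, which encodes cyclooxygenase, 14.8-fold higher pooled but 2-fold higher in only 4 of 8 clusters (0.0786 in G5, near the wild-type 0.0771, to 3.02 in G12).

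Interferon response genes had 14 of 18 members lower and none higher (-2.18, percentile 0). Ifi27l2a and Isg15, both interferon-induced, were 83.9-fold and 27.5-fold lower pooled and at least 2-fold lower in all 8 clusters. MHC class II genes, which present antigen, had 5 of 6 lower (-2.03, percentile 0.01), with the invariant chain Cd74 6.20-fold lower. This result was not firm. Cd74 also differed between W0 (4.45) and W1 (1.41), and without W0, G12 and G14 the list median was -0.91 and no longer stood apart. The macrophage gene C1qa, picked after its values were seen, went the same way (0.104 against 0.331, with 0.598 in W0 and 0.0379 in W1), so RNA of macrophages in W0 was not excluded. Cell cycle genes had 15 of 22 lower (-1.40, percentile 0), but this rested on cluster W2 with 5 cells, and without it the median was -0.55 and no longer stood apart. The alternative macrophage list had 4 of 6 lower and 2 higher (-1.06, percentile 1.25), led by Apoe and by Spp1, which encodes osteopontin and is also a duct marker, at 3.47-fold lower (2-fold in 5 of 8 clusters). Its place outside the random lists was lost with UMIs per 10000 UMIs, with the mean of members and without W0, G12 and G14.

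Lists that did not stand apart from the random ones were unfolded protein response (1 of 19 higher and 3 lower, median -0.39), Notch and Wnt targets (1 of 9 and 4, -0.71) and YAP targets (2 of 10 and 4, -0.17). The same held for EMT genes (4 of 11 and 1, -0.25), extracellular matrix and myofibroblast genes (5 of 12 and 4, -0.30), inflammatory fibroblast genes (2 of 10 and 5, -0.81) and sex-linked genes (0 of 4 and 1, -0.78). With the mean of members the extracellular matrix list stood apart on the higher side (0.62), and without W0, G12 and G14 the inflammatory fibroblast list on the lower side (-1.12). The T cell activation and erythroid lists had only 1 and 2 measured members, and the mitochondrially encoded list had none, as the table had no rows for those genes. The median over all 5203 genes compared was -0.27, and 33.1% of genes at least 2-fold apart were higher in G12D. Between W0 and W1, clusters of 51 and 41 cells in the same library, 230 of 5197 genes were 2-fold apart.

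**Figure D1:**
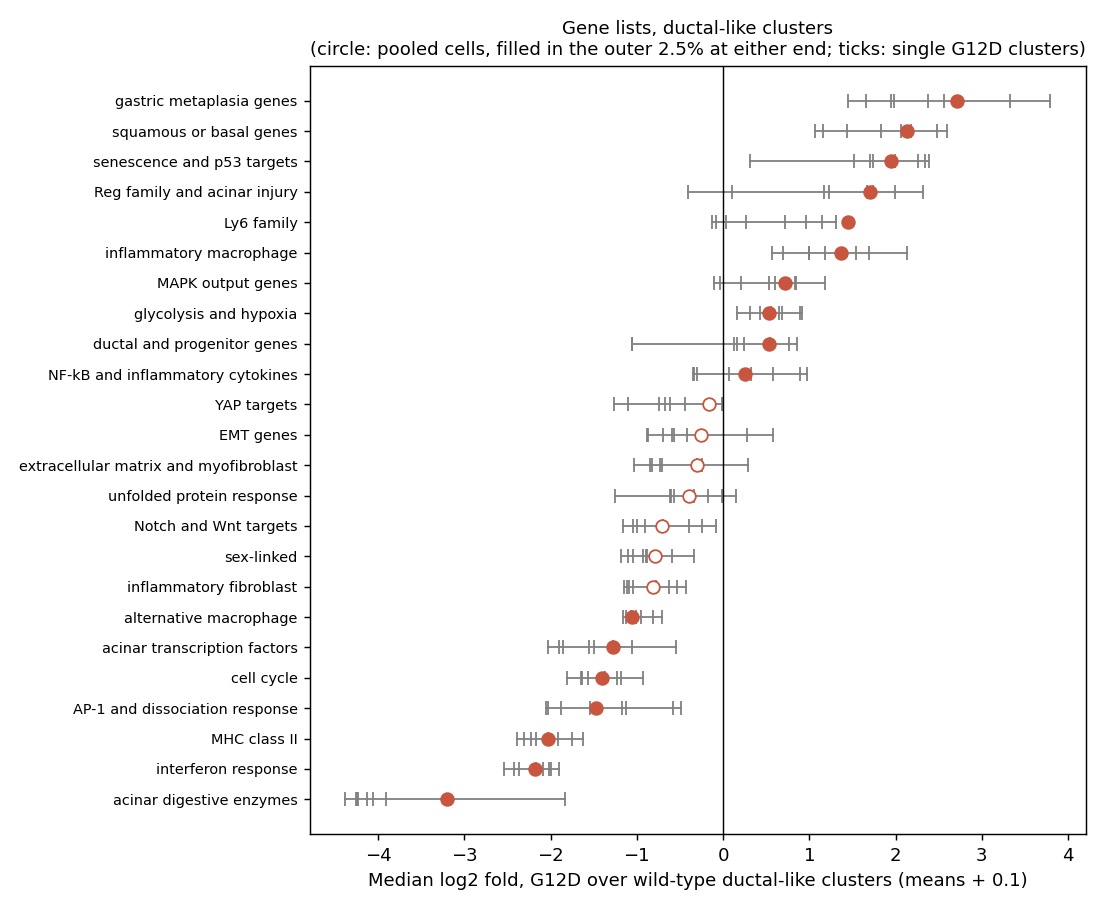
Median log2 fold of each gene list between the G12D and the wild-type ductal-like clusters (x axis, mean scaled levels plus 0.1), with 1 list per line. Circles stand for pooled cells and are filled where the list lay in the outer 2.5% of its random lists at either end, grey ticks for each of the 8 G12D clusters against the pooled wild-type clusters. The gastric metaplasia list lies highest at 2.71 and the enzymes lowest at -3.20, and the 8 clusters fall on the same side of 0 in both.

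The series is about Ly6d, so its detection was measured in each group and cluster, beside Kras, the mutated gene. Ly6d lies on chromosome 15 from 74762056 to 74763620 on the minus strand (GRCm38/mm10 annotation), and Kras on chromosome 6 from 145216699 to 145250239, also on the minus strand; both are protein-coding. Ly6d UMIs were found in 34.0% of G12D cells (31.0 to 37.0%) and 3.00% of wild-type cells (1.22 to 6.09%). The Ly6d level was 2.94 against 0.0620, 47.3-fold higher in G12D (38.3 to 59.2). Kras UMIs were found in 80.4% of G12D and 33.0% of wild-type cells, at levels of 2.42 and 0.380, 6.37-fold higher (5.46 to 7.48). With each cell thinned to 5000 UMIs, which left 872 G12D and 210 wild-type cells, the shares were 20.4% and 1.43% for Ly6d and 54.5% and 11.9% for Kras.

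Within the G12D library Ly6d was concentrated in a few clusters. G5, with 30 cells (2.96% of the library), held 46.6% of the 6089 Ly6d UMIs, at a level of 43.0 and with a UMI in 96.7% of cells. The gastric mucous-like clusters held 31.7% of the UMIs, at a level of 5.71, and 62.6% of their cells had one. Over the ductal-like clusters the level was 2.90 against 0.149 in wild type, 19.4-fold higher (15.7 to 24.3), but 4 of the 8 clusters were 2-fold higher and the range ran from 0.0367 in G11 to 43.0 in G5. Without G5 the G12D level was 0.826. Ly6d is among the gastric markers used to name clusters and among the leading genes of G5, so its height in those clusters is partly a matter of how they were defined.

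The wild-type value rested on few cells. Ly6d was seen in 7 wild-type cells with 87 UMIs, all ductal-like, and 1 cell of cluster W1 held 79 of them. Ly6d UMIs were seen in 0 of 91 wild-type acinar-like cells (allowing up to 3.30% of cells with a UMI, at a median depth of 12270 UMIs, which does not limit the cells that express it) and in 7.81% of the intestinal-led G12D cells, whose level was 0.0401. In clusters G7, G11, G14 and G15, 15.6%, 8.41%, 6.45% and 8.18% of cells had one, at levels of 0.114 or less.

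Kras followed another order. It was highest in G15 (5.81, Poisson interval 5.48 to 6.17) and G14 (4.78, 4.40 to 5.18) and lowest among the G12D ductal-like clusters in G5 (0.505, 0.350 to 0.705). Pooled, the ductal-like level was 3.17 against 0.382, 8.31-fold higher (6.89 to 10.1), and 7 of 8 clusters were 2-fold higher. The wild-type acinar-like cells had 0.336 and the gastric mucous-like G12D cells 1.52. The deposited counts do not separate mutant from wild-type Kras transcripts, so these levels do not check the genotype labels. The 3-prime end of Kras overlaps the neighbouring gene Etfrf1 in the annotation, and Etfrf1 had a level of 0.106 in G15.

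**Figure D2:**
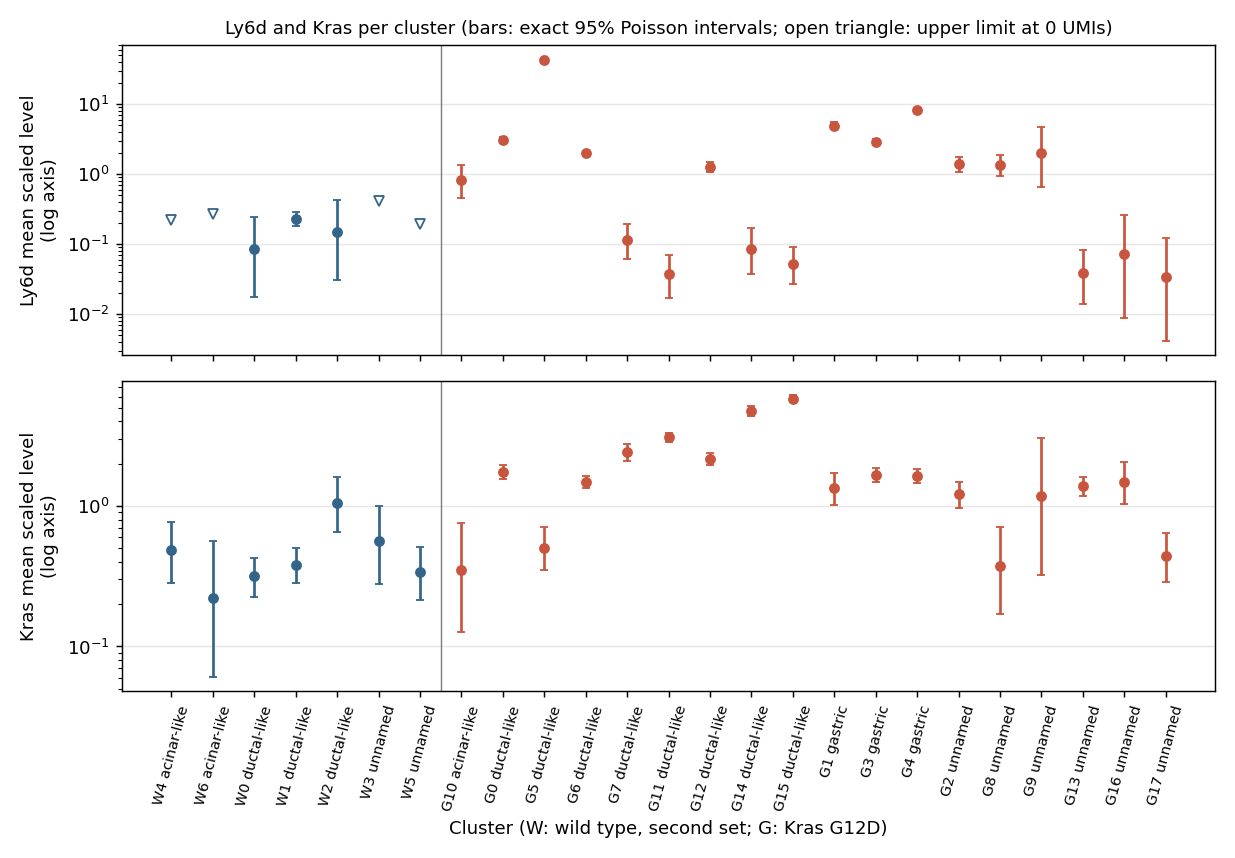
Mean scaled level of Ly6d (top) and Kras (bottom) on log axes in each of the 7 wild-type clusters (W, blue) and 18 G12D clusters (G, red), with exact 95% Poisson intervals as bars and open triangles for the upper limit where no UMI was counted. Ly6d peaks in G5 at 43.0, where Kras is at 0.505, and Kras peaks in G15 at 5.81, where Ly6d is at 0.0518.

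The last comparison asked how Ly6d-positive epithelial cells differed from Ly6d-negative ones inside the G12D library. Of its 801 ductal-like and gastric mucous-like cells, 299 had a Ly6d UMI and 502 had none. Of the 299 cells 79 held a single UMI. The 10 intestinal-led cells with Ly6d also held 1 UMI each, as free RNA would give, so a cell called positive need not express the gene. With at least 3 UMIs required (185 cells), 23 of the 24 named genes passed, all but Pnliprp1. Gastric metaplasia genes were higher in the positive cells, while several extracellular matrix genes, though not the collagens, were lower. Dmbt1 was 5.92-fold higher (35.7 against 6.03), Tff1 4.81-fold, Gkn1 4.44-fold, Gkn2 5.21-fold and Reg1, a secreted regenerating protein, 4.55-fold higher. Fn1 was 6.31-fold lower (5.44 against 34.3), but its median log2 fold within clusters was 0.26, in the opposite direction. Kras was 1.88-fold lower, at 1.79 against 3.37, which is under 2-fold and fell to a median log2 fold of -0.26 within clusters.

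Olfm4, a marker of gut stem and injured epithelial cells, was 13-fold higher in the positive cells, and Sprr2a3, a cornified-envelope gene, 6.82-fold. The glutathione transferases Gsta3 and Gsta1 were 6.41-fold and 6.35-fold higher, and Sult1c2 (a sulfotransferase), Sptssb (a sphingolipid enzyme subunit) and Pnliprp1 (a lipase-related protein) were 6.96-fold, 6.23-fold and 8.54-fold higher. Among genes lower in positive cells, Xirp2 was 117-fold lower, the gut hormone gene Pyy 16.4-fold, the cytokine Csf2 6.48-fold, and the activin subunit Inhba 6.07-fold lower. Xirp2 had 4 UMIs in the positive cells and a median log2 fold of 0 within clusters. Pnliprp1, Pyy, Ctla2a and Ggct ran the opposite way within clusters, with values given below. Hmga2, a chromatin protein of fetal and tumor tissue, was 5.69-fold, Sox11 5.39-fold, Ctla2a 4.90-fold and the laminin Lamb1 6.62-fold lower. Crlf1 (a cytokine receptor-like factor), Ggct (a glutathione-cycle enzyme) and Cpe (carboxypeptidase E) were 6.14-fold, 5.19-fold and 4.78-fold lower.

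Of the lists, gastric metaplasia genes had 15 of 24 members higher in the positive cells (median log2 fold 1.27, percentile 100), and the acinar digestive enzymes 11 of 16 higher and 1 lower (1.22, percentile 100). The Reg family and acinar injury list had 5 of 10 higher (0.97, percentile 100). Extracellular matrix genes had 5 of 9 lower (-1.04, percentile 0), EMT genes 4 of 8 lower (-0.87, percentile 0.01) and YAP targets 2 of 10 lower (-0.76, percentile 0). The other lists that stood apart had few members 2-fold apart, namely cell cycle (3 of 22 higher, 0.60, percentile 100), unfolded protein response (1 of 19 higher, 0.56, percentile 99.99), MHC class II (0 of 4, 0.44, percentile 98.4) and Notch and Wnt targets (1 of 8 lower, -0.46, percentile 0.32). The positive cells were deeper, with a median of 28301 UMIs against 14952. In 258 pairs matched within 10% of genes detected, 23 of the 24 named genes still passed, though these were chosen for large folds. In ductal-like cells only, 24 passed, and with pseudocount 1, 18 passed. The split also followed the clusters, since within G1 (of low depth), G6 and G12, which held at least 20 cells of each kind, only 6 of the 24 named genes kept a 2-fold median difference. The directions of Pnliprp1, Pyy, Fn1, Ctla2a and Ggct were opposite there, with median log2 folds of -0.93, 0.23, 0.26, 0.22 and 0.35. Of all 330 genes at least 2-fold apart, 20 had a median 2-fold apart within clusters and 123 ran the same way in all 3. The list values above were taken over all 801 cells and so include differences between clusters.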

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

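The test of free RNA in the intestinal-led clusters and the split of the pancreatic identity genes into 2 pairs were chosen only after the results were seen; the other tests below were written before. Each of the following 4 signals appeared in G12D clusters outside the comparisons, at a share of cells above that in the wild-type library. Clustering fixed much of this beforehand, since Car1, Muc2 and Sfrp1 are among the 10 leading genes of their clusters and C1qa is in the marker list that set G8 apart, so the values describe those clusters only. In the rest of the G12D library Sfrp1 was in 11.9% and C1qa in 14.8% of cells, no higher than in wild type. Car1, a carbonic anhydrase of colonic epithelium, was found in 48.1% of the cells of cluster G13 (39 of 81) and in 0 of 233 wild-type cells. Muc2, the goblet cell mucin, was found in 100% of the cells of cluster G17 (35 of 35) and in 1 wild-type cell. The macrophage complement gene C1qa was found in 71.4% of the cells of cluster G8 (10 of 14), against 16.7% of wild-type cells. Sfrp1, a secreted Wnt inhibitor of fibroblasts, was found in 84.6% of the cells of cluster G9 (11 of 13), against 12.9% of wild-type cells. Among the unnamed clusters, the lymphocyte genes that led G2 rested on few cells, with Gzma in 1 of 43 cells and Ptprc in 13.95%, and the same held for wild-type cluster W5, with Cd2 in 4 of 20 cells.

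Car1 and Muc2 belong to 3 G12D clusters led by intestinal genes (G13, G16 and G17, 128 cells), for which cells of the large bowel in the digested tissue, pancreatic cells with an intestinal program and free RNA were weighed. The colon identity list of 8 genes, led by Hoxb13 (4.50) and Cdx1 (2.65) and with 5 UMIs in the wild-type library, was 281 times the level of the G12D ductal-like clusters (198.7 to 412.6). Free RNA, which would be at a like level in every cluster, was argued against by this. Those genes had not been used to see the pattern, but they could be among the variable genes that formed the clusters. By contrast, the 4 pancreatic identity genes were at 0.686 of the ductal-like level (0.552 to 0.846). By the limit set in advance (at least 0.5) that value would have excluded bowel cells, but it came wholly from Hnf1b and Nr5a2 (ratio 0.982), which intestinal epithelium also uses, whereas Pdx1 and Onecut1 had 0 UMIs in these clusters against 278 in the ductal-like ones (upper limit of the ratio 0.243, just under the 0.25 that was then required). Bowel cells and pancreatic cells that took on an intestinal program therefore cannot be told apart from these genes, no sort in the protocol would have removed bowel epithelium, and the clusters exist in 1 library only.

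Kras differed between G12D ductal-like clusters, from 0.505 in G5 to 5.81 in G15. Scaling or depth does not account for the spread, since Kras UMIs per 10000 UMIs were 10.7 times as high in G15 as in G5 (7.60 to 15.5). Extra copies of the chromosome segment around Kras were tested with the 10 nearest expressed genes. Their median log2 fold was -0.0847 in G15 over the other ductal-like clusters. Its upper limit of 0.51 lay a little under the 0.57 (0.5 of the log2 fold of Kras) set in advance. The test does not decide the question, because the other clusters included G14, where Kras was also high. Some neighbours were also near the pseudocount of 0.1, such as Rassf8 (0.131 against 0.0760), which understates their folds. The 67 genes within 20 Mb had a median of -0.10, but a short segment with Kras alone was not tested. Extra copies and a difference in transcription between the clusters remain open as hypotheses. So does a link to the G12D allele, as the counts do not separate the alleles.

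Acinar enzymes were detected in the wild-type ductal-like cells at 0.691% of the acinar-like level, and each of the 97 cells held some (share of a cell's UMIs from 0.0572% to 24.9%, median 0.523%). Free RNA from acinar cells is consistent with this, because the log2 ratio between the classes had an interquartile range of 0.43 over 29 enzymes, well under the limit of 1 set in advance. Droplets that held an acinar beside a ductal cell cannot be told apart from it, as the upper 50% of cells by enzyme share held 78.4% of the enzyme UMIs, between the limits set for either reading. The enzyme differences between the ductal-like clusters of the libraries may therefore reflect the number of acinar cells in each library, while low expression in duct cells was not tested.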

How the results depend on the processing

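Alternatives chosen after the data were seen were UMIs per 10000 UMIs, the settings that left out clusters, left them unnamed or weighted them equally, the within-cluster medians, the minimum of 3 Ly6d UMIs and the enzyme-free scaling of the lists. Named genes were chosen for large folds, so keeping 2-fold is weak evidence of stability. In the ductal-like clusters all 24 were kept in the 12 alternatives that included them all (1 of them, the second wild-type set alone, identical by construction), and 20 without the enzymes, where 4 were left out by construction. Over all cells 15 were kept without the enzymes (9 left out by construction), and 21 or more otherwise. The percent of genes higher among those 2-fold apart, 64.2% over all cells, was 57.8% with no minimum level, 69.7% with groups rescaled by the median ratio, 27.8% without the enzymes, 56.0% with classes weighted equally and 81.1% with UMIs per 10000 UMIs. The median of all genes shifted by 0.12 with the median ratio, by -0.67 without the enzymes and by 0.41 with UMIs per 10000, so the split over all cells follows the scaling, and folds there are relative to it. In the ductal-like clusters the percent, 33.1%, was 45.1% with pseudocount 1, 29.9% with no minimum, 46.0% with a minimum of 2, 30.1% without cells that carried markers of 2 classes and 30.09% without W0, G12 and G14 (443 and 46 cells left, the second under the planned minimum of 50), while UMIs per 10000 shifted the median by 0.02. The cause was not tested.

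In the G12D library the ductal-like share was 53.9% at resolution 0.5, the gastric mucous-like share 29.4% at 0.5 and 22.9% at 2, and the unnamed share 15.3% and 16.7%. With W0, G12 and G14 left unnamed the ductal-like share was 43.7% in the G12D and 19.7% in the wild-type library and the unnamed share 36.1% and 41.2%, by construction. Without cells that carried markers of 2 classes the wild-type acinar-like share was 60.9% and the unnamed share 0%. That rule marked 42.9% of wild-type and 26.7% of G12D cells, among them every unnamed wild-type cell. The unnamed G12D share was 17.9% under it. Thinned to 5000 UMIs, Ly6d detection was 20.4% in all and 17.9% in ductal-like G12D cells, and Kras detection 54.5% and 64.7% there and 11.9% and 15.6% in wild type. With a level above 1 required, Ly6d was 22.2% and 18.3% in G12D and 0.858% and 2.06% in wild type, and Kras 66.9% and 79.1% against 14.2% and 16.5%. Both rules lower detection by construction, and G12D stayed above wild type. Without W0, G12 and G14 the ductal-like G12D value for Ly6d was 34.5%. Of the 24 genes named for Ly6d-positive cells 6 were kept within clusters, and Pnliprp1 (-0.93), Pyy (0.23), Fn1 (0.26), Ctla2a (0.22) and Ggct (0.35) reversed there. Over all cells the AP-1 list (0.20) and the extracellular matrix list (0.0939) reversed with the mean of members, while the Reg list was weaker there (-0.56). With UMIs per 10000 the matrix list reversed (0.46). The Reg median also crossed 0 in that setting (0.0230), but the Reg list still stood apart on the lower side. In the ductal-like clusters the NF-kB list (-0.00945) reversed without W0, G12 and G14, where the acinar transcription factor, MHC class II and alternative macrophage lists no longer stood apart. Of 265 list values under alternatives, 243 kept their side of the random lists, and of 701 for named genes 473 stayed within their spread and 223 moved in the same direction.

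No paired analysis was possible because cell names do not show which numbered sample a cell came from, so no result has replicates and no replicate was there to leave out. Comparison with the first wild-type set alone was not run, as it had no cells here, and a minimum of 500 genes removed no cell (lowest 605). With 1 library per group, depth limits low genes only, while differences between animals or batches stay unmeasured.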

Other observations

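Interferon-response genes set the 3 wild-type ductal-like clusters apart from every G12D cluster, while the other clusters of the libraries overlapped. The summed scaled level of the 20 listed genes was 14.8 in W0 (Poisson interval 14.01 to 15.6), 15.8 in W1 (15.1 to 16.6) and 14.3 in W2 (12.6 to 16.1). The wild-type acinar-like clusters W4 and W6 were at 2.86 and 3.05, and the unnamed W3 and W5 at 7.17 and 5.38. Over the 18 G12D clusters the level ran from 0.932 in G15 to 6.96 in the intestinal-led cluster G13, with a median of 1.81, and 14 of the 18 lay below the lowest wild-type cluster. G8 (5.01), G13 and G17 (4.61) were above W4 and W6, and G13 was also above W5. G9 (3.64, 1.74 to 6.69) rested on 10 UMIs, and its interval includes the levels of W4 and W6. W3 was above every G12D cluster, but its interval (6.10 to 8.37) includes the level of G13. The G12D acinar-like cluster G10 had 2.23 (1.51 to 3.19), whose interval includes the level of both wild-type acinar-like clusters. Against the pooled wild-type ductal-like cells the list's median log2 fold was below 0 in 18 of 18 G12D clusters, from -2.54 to -1.02. Stat1, a transcription factor of interferon signaling, was at 1.46 in W0, 1.63 in W1, 0.374 in W4 and 0.246 in W6, and at 0.354 in G13, the highest of the G12D clusters.

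Senescence and p53 targets were not equally high in the G12D clusters. Against the pooled wild-type ductal-like cells the list's median log2 fold was 2.39 in G6, 2.34 in G11 and 2.26 in G0, and 0.32 in G5, the cluster with the highest Ly6d level. In the gastric mucous-like clusters G1, G3 and G4 it was 0.93, 1.17 and 0.98, and in the intestinal-led G13 it was 0.14. Cdkn2b had a level of 4.69 in G15 and 0.385 in G5. These values were picked after they were seen.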
